A study of Mus musculus with 18 samples.

How the data were processed

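Liver RNA of 18 male C57BL/6 mice was sequenced, 6 mice in each of 3 groups named Control, Cirrhosis and Cirrhosis-PTH, with 1 library per mouse. The labels' protocols describe 45 mice, 15 per group, of which 18 have libraries in the series. Control mice received corn oil by intraperitoneal injection, 10 µl per g of body weight 2 times a week for 12 weeks. Mice of both other groups received 10% carbon tetrachloride (CCl4), a solvent that injures the liver, in the same volume and schedule. Cirrhosis-PTH mice were also given PTH by mouth each day at 0.25 mg per g from a solution of 50 mg/ml. Control and Cirrhosis mice were given double distilled water by mouth each day instead. No group received corn oil with PTH. The mice were 6 weeks old at purchase. PTH here is Pien Tze Huang, a traditional Chinese medicine, and not parathyroid hormone. The Control libraries carry the replicate numbers 1, 2, 3, 6, 7 and 8, and the libraries of the other groups carry 1 to 6. Libraries were made from total RNA after removal of ribosomal RNA, per the labels' protocols.

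The deposited values are whole-number counts per gene in 1 table of 54752 genes, each given by its Ensembl identifier and symbol, with 1 column per library. The submitters' processing notes name the mouse genome build GRCm38 and the tools HISAT2 2.2.1, StringTie 2.1.5, cutadapt 4.2, Bowtie 1.3.1, Bowtie2 and Trim Galore, without a role or order for any of them. The strandedness of the counting, the annotation release and any filter on reads or genes are not stated. The column totals differ between libraries, so the counts had not been scaled before they were deposited. Totals ran from 62482144 to 112294112 counts per library. A share of those counts came from loci that collect ribosomal RNA reads (Gm42418, Gm26917, CT010467.1, Lars2 and the mitochondrial ribosomal RNA genes), and from 24.5 M to 67.5 M counts per library lay elsewhere.

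All libraries entered 1 fit of 3 groups in edgeR 4.0.16 under R 4.3.3, so that the comparisons share 1 estimate of the spread. Genes were kept by filterByExpr with its default settings, which left 21914 genes, and 18354 genes of the table had no count in any library. Library sizes were scaled by the trimmed mean of M values (TMM). Each gene was tested with the robust quasi-likelihood F-test, two-sided, and the p-values of a comparison were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Every adjusted p of a gene is from that test. Levels are CPM, each deposited count divided by the TMM-scaled library size in M counts, and are given as mean ± SD over the 6 mice of a group. Log2 fold changes carry their standard error (SE), derived from the F statistic. For a gene without a count in 1 group, the fold is a bound computed against a floor of 3 counts over that group. A gene with 3 counts in a group is given as a ratio with its 95% interval. Reads were not counted as molecules, so such bounds and intervals cover counting error only. List medians were the same with such genes at their bound.

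A total of 45 gene lists (cell type markers, pathways and complexes of the liver) were fixed before the data were examined, as were the comparisons, the tests and the first set of alternatives. A list needed 5 tested members, and 42 lists had them. Exocrine pancreas, adipocyte and striated muscle markers had 2, 4 and 2 tested members and were not tested. Each list was tested against the other genes with camera of limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. The estimated correlation between genes and fry were alternatives. With the estimated correlation, 4 lists kept their call in Cirrhosis against Control (male-biased liver, pericentral hepatocyte, fetal and tumour-associated liver, and p53 target) and 1 in Cirrhosis-PTH against Cirrhosis (p53 target). No list did in Cirrhosis-PTH against Control, where 7 of 42 had an unadjusted p under 0.05 and fry called 25. A list score is the mean log2 CPM over a list's members in a library, each member centred on the Control mean. Scores were compared with a two-sided exact permutation test over the 924 arrangements of 6 against 6 libraries, whose smallest p is 0.0022, with adjustment over all lists and comparisons. Counts of changed members are given over all genes tested and, where so worded, adjusted over the list alone.

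Long noncoding RNA (lncRNA) genes were those with such a biotype in GENCODE mouse release 21, matched by identifier for 54723 of the genes in the table. Their coordinates are on GRCm38. The genes named in each comparison were chosen by a rule set before the data were examined. The rule takes the 6 genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean log2 CPM of at least 1, an established symbol and no overlap between the groups' libraries. It adds the members with the smallest p of the 10 leading lists, 3 lncRNA genes per direction and the 6 leading genes per direction of those that changed oppositely. The genes Col1a1, Acta2, Timp1, Cyp2e1, Cyp7a1, Cyp2b10, Alb and Krt19 are given whatever their result.

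The quasi-likelihood steps were tested on simulated counts drawn from these libraries' means and sizes, with 21499 genes tested in the simulation and 50 genes changed at each of 4 fold sizes. The changed genes were drawn from those with a mean log2 CPM above 0, so the shares do not cover genes of lower level. With so few genes changed, the simulation also does not test the scaling where a large part of the genes move. For Cirrhosis against Control the fit recovered 44% of the genes changed 1.5-fold, 88% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 8 false calls among 173. For Cirrhosis-PTH against Cirrhosis the shares were 44%, 82%, 96% and 100%, with 5 false calls among 166. In a simulated shift of the cell cycle list among 42 lists, camera called that list and 0 others. Alternatives were RLE and upper-quartile scaling, no filter, a filter at a CPM of 1 in 6 libraries, DESeq2 1.42.0, limma voom, the non-robust fit, fits of 12 libraries, the replicate number as a block, each library left out in turn, abundant genes left out, a test against a fold change of 1.5 and a prior count of 0.5. Alternatives chosen after seeing the data left out Control replicates 7 and 8, thinned all libraries to 24513979 counts, or left out the ribosomal RNA loci before scaling. No pair of libraries within a group was a copy of another, with 0 of 45 pairs identical.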

Results

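The series profiled liver RNA in mice with chemically induced cirrhosis, with and without daily oral PTH, and in corn oil controls. There were 6 mice per group, each with its own library, and each mouse was sampled once, after 12 weeks. The mean total was 78.9 ± 18.3 M counts in Control, 87.5 ± 7.88 M in Cirrhosis and 87.5 ± 9.07 M in Cirrhosis-PTH (SD, n = 6 each). The locus that collects most ribosomal RNA reads held 28.2 ± 5.94% of the counts in Control, 20.5 ± 2.05% in Cirrhosis and 22.7 ± 4.65% in Cirrhosis-PTH. The first difference passed an exact permutation test (two-sided adjusted p = 0.0195), and Cirrhosis-PTH against Cirrhosis gave an adjusted p of 0.40 in the same exact test. All loci that collect ribosomal RNA reads together held 47.8 ± 7.29% in Control, 38.7 ± 1.73% in Cirrhosis and 41.1 ± 6.31% in Cirrhosis-PTH. The share was highest in Control replicates 7 and 8, at 50.9% and 60.8%, which left 31.0 M and 24.5 M counts elsewhere. More genes had at least 10 counts in Cirrhosis, 22079 ± 461, than in Cirrhosis-PTH, 20946 ± 696 (exact permutation adjusted p = 0.0195), or Control, 19238 ± 1014 (exact permutation adjusted p = 0.0195).

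Along an axis running from the mean Control liver at 0 to the mean Cirrhosis liver at 1, Cirrhosis-PTH livers took a middle place. Each library was placed with group means that left that library out. The positions were 0.0701 ± 0.0684 in Control, 0.965 ± 0.0815 in Cirrhosis and 0.418 ± 0.108 in Cirrhosis-PTH (SD, n = 6), and the Cirrhosis-PTH mice ran from 0.318 in replicate 1 to 0.569 in replicate 3. The first principal component held 41.7% of the variance. All 6 Cirrhosis-PTH libraries lay between the Control and the Cirrhosis libraries along it. On the second component, with 8.82% of the variance, Control replicates 7 and 8 lay apart from the other Control libraries at 53.6 and 71.5, against a highest value of 13.4 among the other 4. All 6 Cirrhosis-PTH libraries lay at its low end, from -56.4 to -21.0. The lowest library of the other groups was at -8.79, so along this component Cirrhosis-PTH lay outside both groups.

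The comparison of Cirrhosis with Control asks what 12 weeks of CCl4 did to the liver. Genes of hepatocytes around the central vein fell. Slc1a2, a glutamate transporter of those cells (ENSMUSG00000005089, GRCm38 chromosome 2, 102658659 to 102790784), fell from 250.2 ± 22.2 CPM in Control to 0.460 ± 0.191 CPM in Cirrhosis (SD, n = 6), a log2 change of -9.08 ± 0.27 (SE, adjusted p = 5.1e-14). Glul, glutamine synthetase, fell from 688 ± 88.4 to 60.5 ± 5.81 CPM (log2 -3.51 ± 0.12). Cyp2e1, the cytochrome that converts CCl4 to its reactive form (ENSMUSG00000025479), fell from 4161 ± 851 to 311 ± 108 CPM (log2 -3.74 ± 0.22). Of the 20 pericentral genes, 18 fell and the other 2 did not pass, with the same count adjusted over the list alone. Their median change was -1.91 (camera adjusted p = 9.8e-12, and adjusted p = 0.037 with an estimated correlation). The 21 periportal genes had a median of -0.67, with 14 lower and 1 higher (15 and 1 adjusted over the list alone), and camera adjusted p = 0.00049 (adjusted p = 0.32 with an estimated correlation).

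Genes with higher expression in male than in female liver fell together. All 21 of the 21 tested members fell, over all genes and adjusted over the list alone, with a median of -2.90 (camera adjusted p = 2.3e-15, and adjusted p = 0.037 with an estimated correlation). Hsd3b5, a steroid-metabolising enzyme, fell from 128 ± 41.2 to 0.191 ± 0.124 CPM (log2 -9.42 ± 0.49, adjusted p = 3.6e-10). Moxd1 fell from 33.2 ± 24.0 to 0.0126 ± 0.0195 CPM (log2 -11.28 ± 1.0), and its value was -11.94 without Cirrhosis replicate 1 and -11.92 without Cirrhosis replicate 3. Elovl3, a fatty acid elongase, changed by -5.79 ± 0.25, and Nudt7, a peroxisomal coenzyme A hydrolase, by -3.42 ± 0.20. The major urinary protein genes Mup12 and Mup17 changed by -8.48 ± 0.81 and -7.59 ± 0.94, and without Cirrhosis replicate 2 Mup12 changed by -9.48. Fitm1, a lipid droplet protein gene, changed by -6.54 ± 0.40. Mup genes are near-identical copies, so the share of reads given to each is uncertain. Among 17 female-biased genes, 7 rose and 1 fell, with equal counts adjusted over the list alone and a median of 1.1. Their camera adjusted p was 0.034, with adjusted p = 0.29 with an estimated correlation. The call of the female-biased liver list in Cirrhosis vs Control did not hold without Control replicate 8, without any 1 Cirrhosis or Cirrhosis-PTH library, without both Control replicates 7 and 8, or with the replicate block, at adjusted p-values from 0.0651 to 0.210.

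Genes of broad hepatocyte functions fell too. Of 38 nuclear genes of oxidative phosphorylation, 37 fell by either count, over all genes or adjusted over the list alone, with a median of -0.73 (camera adjusted p = 2.3e-15, and adjusted p = 0.12 with an estimated correlation). Sdha of complex II and Ndufb8 of complex I changed by -0.93 ± 0.08 and -0.81 ± 0.07. Coagulation and complement genes fell in 23 of 27 members, also adjusted over the list alone, with a median of -0.85 (camera adjusted p = 4.9e-12, and adjusted p = 0.13 with an estimated correlation). Proc, which encodes protein C, changed by -1.11 ± 0.07, and C8b of the terminal complement complex by -1.83 ± 0.14. Of 34 urea cycle and amino acid catabolism genes, 27 fell (28 adjusted over the list alone), with Agxt at -1.44 ± 0.13 and Otc at -1.18 ± 0.11. That list had a median of -0.82 (camera adjusted p = 9.6e-10, and adjusted p = 0.25 with an estimated correlation).

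In the bile acid list, 28 of 33 members fell and 2 rose, the same numbers adjusted over the list alone, with a median of -1.15 (camera adjusted p = 2.4e-10, and adjusted p = 0.081 with an estimated correlation). The sterol transporters Abcg8 and Abcg5 changed by -2.24 ± 0.11 and -1.92 ± 0.12, while Slc10a2, a bile acid uptake transporter, rose by 2.08 ± 0.18. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 174 ± 50.6 to 51.1 ± 46.1 CPM (log2 -1.77 ± 0.55, adjusted p = 0.014). Of 39 cytochrome P450 genes of families 1 to 3, 29 fell and 4 rose, as also adjusted over the list alone, with a median of -1.09 (camera adjusted p = 1.9e-08, and adjusted p = 0.13 with an estimated correlation). Cyp2b10 rose from 0.218 ± 0.226 to 3.92 ± 3.92 CPM (log2 4.10 ± 0.86, or 3.49 without Cirrhosis replicate 3). Alb, the albumin gene, changed by -0.44 ± 0.14 (adjusted p = 0.013), a call that did not hold in the fit of 12 libraries. Secreted hepatocyte protein genes fell in 19 of 20 members by both counts, also adjusted over the list alone. Their median was -0.71 (camera adjusted p = 3.8e-09, and adjusted p = 0.13 with an estimated correlation).

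Matrix genes and genes of recruited macrophages rose. Col1a1, a chain of type I collagen (ENSMUSG00000001506), rose from 13.3 ± 12.7 to 206 ± 45.3 CPM (log2 3.96 ± 0.55, adjusted p = 1.7e-05), and the change was 4.65 without Control replicate 7. Of 31 fibrillar and matrix genes, 29 rose, with a median of 2.22 (camera adjusted p = 3.6e-13, and adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 29 rose and 1 fell. Col4a1 and Col4a2, basement membrane collagens, rose by 2.33 ± 0.12 and 2.06 ± 0.12, and the fibrillin gene Fbn2 rose by 7.71 ± 0.71 (8.60 without Control replicate 7). All 24 of 24 matrix crosslinking and remodelling genes rose, also adjusted over the list alone, with a median of 2.57 (camera adjusted p = 4.3e-13, and adjusted p = 0.095 with an estimated correlation). Adamts12 rose by 3.88 ± 0.20 and Mmp14 by 1.59 ± 0.09. Mmp7 rose by 6.69 ± 0.96, or 8.22 without Control replicate 3. Timp1, an inhibitor of matrix proteases, rose by 4.79 ± 0.78, or 6.93 without Control replicate 7, and Acta2, a myofibroblast actin, by 1.85 ± 0.40. Stellate cell and myofibroblast genes rose in 18 of 25 members and fell in 1 (19 and 1 adjusted over the list alone), with camera adjusted p = 7.2e-06 (adjusted p = 0.13 with an estimated correlation).

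Of 20 recruited macrophage genes, 19 rose (20 adjusted over the list alone), with a median of 3.28 (camera adjusted p = 4.9e-12, and adjusted p = 0.081 with an estimated correlation). The integrin gene Itgax rose by 3.53 ± 0.22 and the galectin-3 gene Lgals3 by 4.54 ± 0.28. Among 29 cytokine and chemokine genes, 27 rose and 1 fell, as also adjusted over the list alone, with a median of 2.34 (camera adjusted p = 3.7e-10, and adjusted p = 0.081 with an estimated correlation). Vcam1 rose by 2.12 ± 0.15 and Tlr2 by 1.66 ± 0.13, and Cxcl12 changed by -0.69 ± 0.12. The duct marker Krt19 rose from 0.398 ± 0.258 to 1.69 ± 0.345 CPM (log2 2.09 ± 0.42), and 14 of 18 cholangiocyte and ductular genes rose while 1 fell, also adjusted over the list alone. That list had a median of 1.87 (camera adjusted p = 6.3e-05, and adjusted p = 0.20 with an estimated correlation).

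Stress, p53, growth and fetal liver genes also rose. Of 20 p53 target genes, 15 rose and 1 fell by either count, over all genes or adjusted over the list alone, with a median of 1.08 (camera adjusted p = 4.5e-06, and adjusted p = 0.024 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose from 0.690 ± 0.194 to 21.8 ± 4.14 CPM (log2 4.96 ± 0.26). Genes of the unfolded protein and integrated stress response rose in 20 of 25 members and fell in 1, also adjusted over the list alone, with camera adjusted p = 7.6e-07 (adjusted p = 0.13 with an estimated correlation). Slc7a11, the cystine transporter, rose from 0.103 ± 0.0847 to 47.9 ± 22.9 CPM (log2 8.80 ± 0.68). Sprr1a, a small proline-rich protein gene, had 3 counts in Control, and its Cirrhosis level was 3451 times as high (95% counting interval 1181 to 16736). The fitted change of Sprr1a was 11.57, and without Control replicate 6, which held those 3 counts, it was at least 2547-fold higher. Vmn2r3, a vomeronasal receptor gene without a count in Control, was at least 1070-fold higher. Ly6d rose by 6.87 ± 0.48. Of 40 cell cycle genes, 30 rose and 1 fell (31 and 1 adjusted over the list alone), with camera adjusted p = 8.1e-08 (adjusted p = 0.099 with an estimated correlation). Fetal and tumour-associated genes rose in 17 of 20 members and fell in 1, also adjusted over the list alone, with camera adjusted p = 1.3e-07 (adjusted p = 0.037 with an estimated correlation).

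Across the transcriptome, 11073 of 21914 genes differed between Cirrhosis and Control, 5591 higher and 5482 lower in Cirrhosis, and 4870 of them differed at least 2-fold (3117 higher, 1753 lower). In 6646 genes the libraries of both groups did not overlap, where chance gives 0.216% of genes, or 47.4. Without Control replicates 7 and 8, 10576 genes differed, and with thinned counts 10451 did. Of 42 lists, 34 were called, 19 up and 15 down, and 4 were called with an estimated correlation. The exact permutation test of the scores called 36 lists. It alone called the endothelial (score adjusted p = 0.0042), AhR target (0.0042), gluconeogenesis (0.019) and named lncRNA (0.0042) lists, and camera alone the CAR and PXR target (0.22) and fatty acid oxidation (0.40) lists. Abcg5 and Abcg8, Col4a1 and Col4a2, and Timp1, Elovl3, Hsd3b5, Glul and Ndufb8 overlap another gene in the annotation, and without a stated strand part of their reads may belong to that gene.

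**Figure D1:**
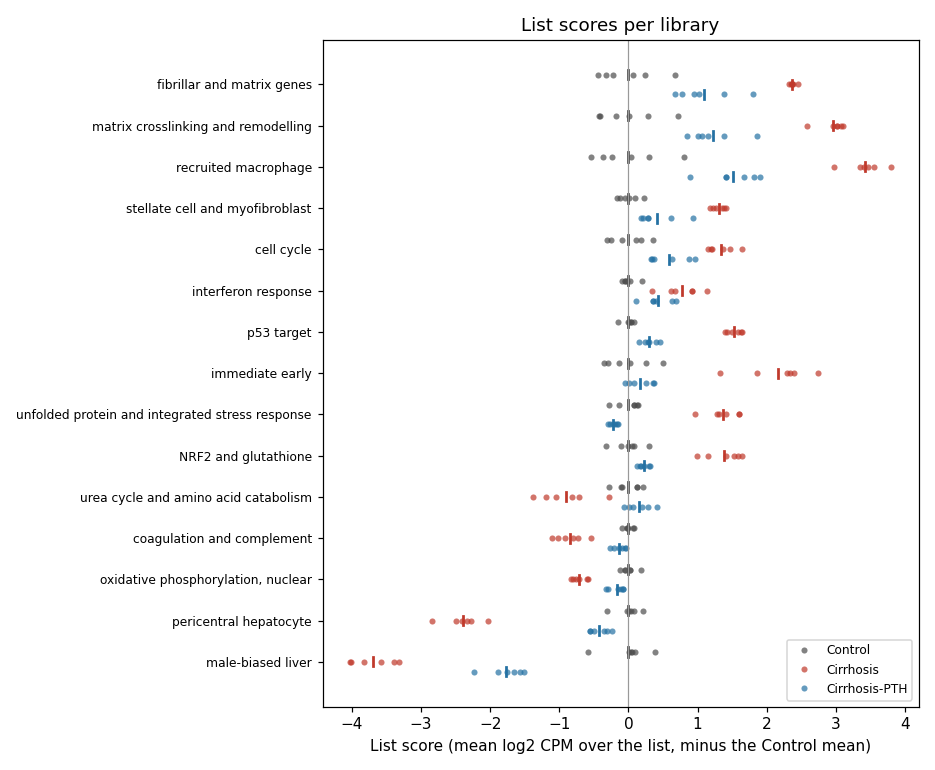
Score of 15 gene lists (horizontal axis, mean log2 CPM over a list minus the Control mean) in each of the 18 libraries, with 1 point per mouse and a bar at the mean of each group of 6. Control scores centre on 0. The p53 target score was 1.53 ± 0.10 in Cirrhosis and 0.30 ± 0.11 in Cirrhosis-PTH (SD), and the score of fibrillar and matrix genes was 2.37 ± 0.05 and 1.1 ± 0.42.

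The comparison of Cirrhosis-PTH with Cirrhosis asks what daily PTH changed in mice given CCl4. Pericentral genes were higher in Cirrhosis-PTH. Slc1a2 was 164 ± 42.4 CPM against 0.460 ± 0.191 CPM in Cirrhosis (SD, n = 6), a log2 change of 8.47 ± 0.26 (SE, adjusted p = 2.4e-13). Glul was 444 ± 69.4 CPM (log2 2.88 ± 0.12) and Cyp2e1 3175 ± 464 CPM (log2 3.35 ± 0.22, adjusted p = 1.5e-09). Of 20 pericentral genes, 18 rose by either count, over all genes or adjusted over the list alone, with a median of 1.54 (camera adjusted p = 1.4e-12, and adjusted p = 0.055 with an estimated correlation). Of 39 cytochrome P450 genes, 30 rose and 2 fell (32 and 2 adjusted over the list alone), with a median of 1.08 (camera adjusted p = 4.8e-12, and adjusted p = 0.090 with an estimated correlation). Cyp2j5 rose by 1.21 ± 0.08, and Cyp2a4 changed by -2.77 ± 0.65, or -2.18 without Cirrhosis replicate 5. Cyp2b10 changed by -2.52 ± 0.76, or -1.90 without Cirrhosis replicate 3 and -3.26 without Cirrhosis-PTH replicate 6, and that call did not hold with the replicate block. The male-biased genes rose in 18 of 21 members (19 adjusted over the list alone), with a median of 1.79 (camera adjusted p = 1.6e-11, and adjusted p = 0.070 with an estimated correlation).

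Single genes of that list (Hsd3b5, Elovl3 and Nudt7) and others outside it rose from a low level in Cirrhosis. Hsd3b5 was 7.73 ± 3.66 CPM in Cirrhosis-PTH against 0.191 ± 0.124 CPM (log2 5.36 ± 0.44), and Elovl3 and Nudt7 rose by 4.06 ± 0.23 and 2.36 ± 0.19. Mup12 rose by 5.79 ± 0.72, or 6.78 without Cirrhosis replicate 2, and Mup17 by 3.90 ± 0.79, or 3.20 without Cirrhosis-PTH replicate 1. Vmn1r90, a vomeronasal receptor gene, rose by 3.48 ± 0.96, a call that did not hold with the replicate block. Its level varied in Control, at 0 CPM in replicates 3 and 6 and 9.03 to 17.4 CPM in the other Control libraries. Alb did not pass, with a change of 0.17 ± 0.14 (adjusted p = 0.37).

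Metabolic hepatocyte genes rose as well. Of 38 nuclear oxidative phosphorylation genes, 35 rose (36 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 2.0e-14, and adjusted p = 0.10 with an estimated correlation). Sdha and Ndufb5 rose by 0.82 ± 0.08 and 0.75 ± 0.08. Urea cycle and amino acid catabolism genes rose in 30 of 34 members (31 adjusted over the list alone), with a median of 1.06 (camera adjusted p = 2.5e-14, and adjusted p = 0.16 with an estimated correlation). Hgd and Hpd, enzymes of tyrosine breakdown, rose by 1.06 ± 0.10 and 1.51 ± 0.15. Coagulation and complement genes rose in 23 of 27 members (24 adjusted over the list alone), among them Proc (0.91 ± 0.07) and C2 (1.04 ± 0.09). Their camera adjusted p was 1.3e-12, with adjusted p = 0.10 with an estimated correlation. In the bile acid list 27 of 33 genes rose and 3 fell, as also adjusted over the list alone (camera adjusted p = 7.1e-11, and adjusted p = 0.070 with an estimated correlation). Abcg8 and Abcg5 rose by 1.66 ± 0.11 and 1.65 ± 0.12, Abcc4, an export pump of the basolateral membrane, changed by -2.69 ± 0.28, and Cyp7a1 rose by 2.1 ± 0.56 (adjusted p = 0.0067).

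Stress genes fell in Cirrhosis-PTH. Hspa5, the chaperone BiP, was 228 ± 18.3 CPM against 823 ± 151 CPM in Cirrhosis and 275 ± 49.4 CPM in Control, a log2 change of -1.85 ± 0.13 against Cirrhosis. Of 25 genes of the unfolded protein and integrated stress response, 24 fell by either count, over all genes or adjusted over the list alone, with a median of -1.52 (camera adjusted p = 8.0e-14, and adjusted p = 0.062 with an estimated correlation). Creld2 changed by -2.38 ± 0.16, and the stress-induced gene Nupr1 by -5.44 ± 0.60. Cdkn1a fell from 21.8 ± 4.14 to 1.33 ± 0.546 CPM (log2 -4.04 ± 0.24, adjusted p = 8.4e-10), and 15 of 20 p53 target genes fell while 1 rose, also adjusted over the list alone. The p53 list had camera adjusted p = 1.2e-06 (adjusted p = 0.015 with an estimated correlation). Slc7a11 fell to 0.471 ± 0.380 CPM (log2 -6.67 ± 0.56). Sprr1a had no count in Cirrhosis-PTH and was at least 4855-fold lower than in Cirrhosis, and Vmn2r3 changed by -7.73 ± 0.54. Bhlha15, a transcription factor of secretory cells, changed by -4.81 ± 0.42. Immediate early genes fell in 17 of 20 members, also adjusted over the list alone, with a median of -2.06 (camera adjusted p = 1.0e-09, and adjusted p = 0.090 with an estimated correlation).

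Matrix, macrophage and cytokine genes fell too. Col1a1 was 60.5 ± 41.6 CPM in Cirrhosis-PTH, a log2 change of -1.77 ± 0.50 against Cirrhosis (adjusted p = 0.010). Fibrillar and matrix genes fell in 21 of 31 members (23 adjusted over the list alone), with a median of -1.15 (camera adjusted p = 4.0e-10, and adjusted p = 0.17 with an estimated correlation). Matrix crosslinking and remodelling genes fell in 20 of 24 (21 adjusted over the list alone), with Adamts12 at -2.27 ± 0.18 and Mmp14 at -1.03 ± 0.09 (camera adjusted p = 1.1e-10, and adjusted p = 0.10 with an estimated correlation). Timp1 changed by -4.51 ± 0.74 and Acta2 by -2.28 ± 0.40. Recruited macrophage genes fell in 18 of 20 members (20 adjusted over the list alone, camera adjusted p = 1.4e-10, and adjusted p = 0.090 with an estimated correlation). Of 29 cytokine and chemokine genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone), with camera adjusted p = 5.8e-11 (adjusted p = 0.070 with an estimated correlation). Vcam1 and Cxcl16 changed by -1.61 ± 0.14 and -1.15 ± 0.12, and Cxcl12 rose by 0.85 ± 0.12. Trdc, a constant segment of the T cell receptor delta chain, fell from 9.83 ± 6.24 to 0.0479 ± 0.0561 CPM (log2 -7.57 ± 0.92). The duct marker Krt19 did not pass, at -0.04 ± 0.39 (adjusted p = 0.96).

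A total of 8464 genes differed between Cirrhosis-PTH and Cirrhosis, 4396 higher and 4068 lower in Cirrhosis-PTH, 2726 of them at least 2-fold (1168 higher, 1558 lower). The libraries of both groups did not overlap in 5002 genes, where chance gives 47.4 (0.216%). Without Control replicates 7 and 8 in the fit, 8787 genes differed, and with thinned counts 8158 did. Of 42 lists, 30 were called, 14 up and 16 down, and 1 was called with an estimated correlation. The score test called 32 lists. It alone called the B and plasma cell (score adjusted p = 0.013), endothelial (0.0074), mesothelial (0.048), AhR target (0.016) and gluconeogenesis (0.013) lists, and camera alone the CAR and PXR target (0.24), fatty acid oxidation (0.056) and interferon response (0.074) lists. Hpd, Ndufb5, C2, Cxcl16, Abcg5, Abcg8, Timp1, Elovl3, Hsd3b5 and Glul overlap another gene in the annotation, and Cyp2a4 and Cyp2b10 have close paralogs, so their reads may be shared.

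Most genes that differed with PTH moved opposite to their CCl4 change. Of the genes called in both comparisons, 7506 changed in opposite directions, 3542 higher with CCl4 and lower with PTH and 3964 the reverse, and 12 changed in the same direction. Genes of the first kind included Lrrc59 (1.42 ± 0.09 with CCl4 and -1.5 ± 0.09 with PTH), Evl (2.27 ± 0.12 and -1.83 ± 0.12), Gfpt1, which starts hexosamine synthesis (1.49 ± 0.10 and -1.62 ± 0.10), 6430548M08Rik (1.5 ± 0.10 and -1.51 ± 0.10), Ifngr1, an interferon gamma receptor chain (1.61 ± 0.08 and -1.18 ± 0.08), and Cdkn1a. Genes of the other kind included Fam210a (-1.45 ± 0.06 and 1.21 ± 0.06), Wdtc1 (-1.56 ± 0.07 and 1.16 ± 0.07), Hint2 (-1.22 ± 0.08 and 1.22 ± 0.08), Slc1a2 and Glul. Lists chosen independently would share 1038 and 1100 genes in those 2 directions and 2139 in the same direction. Both comparisons use the same Cirrhosis libraries, which alone gives a negative relation. In 20 simulations of unchanged groups edgeR called 0 opposed genes (median 198 at an unadjusted p under 0.05), and the covariance of the log2 changes averaged -0.0603 (correlation -0.486). The observed covariance over 21914 genes was -0.920 (correlation -0.807), and genes are not independent replicates. With separate groups of 3 Cirrhosis libraries for each comparison, in 20 ordered splits, 5174 to 5741 of the same 21914 genes were opposed and the covariance ran from -0.907 to -0.853 (correlation -0.745 to -0.684). Lrrc59, Evl, Fam210a and 6430548M08Rik overlap another gene in the annotation, so their reads may be shared.

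**Figure D2:**
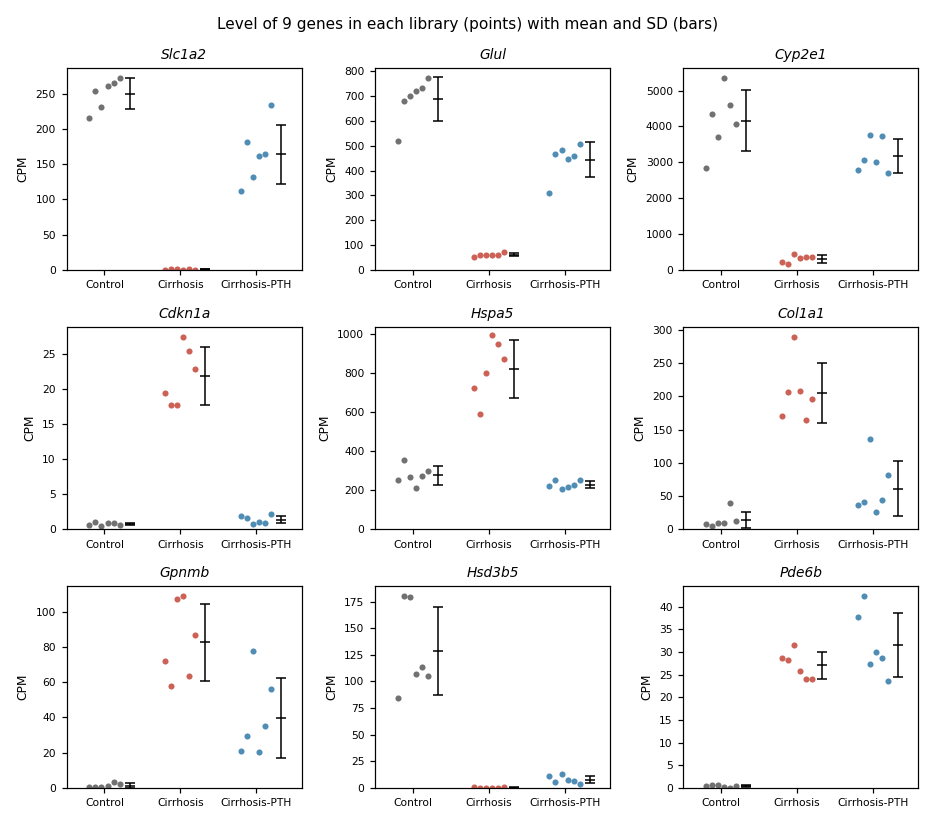
Level of 9 genes (vertical axis, CPM, from 0) in the 6 mice of each group, with 1 point per library and bars for mean and SD. Slc1a2, Glul and Cyp2e1 are low in all 6 Cirrhosis mice and higher in all 6 Cirrhosis-PTH mice, while Hsd3b5 averages 7.73 CPM in Cirrhosis-PTH against 128 CPM in Control, and Pde6b averages 27.1 and 31.6 CPM in the CCl4 groups against 0.379 CPM in Control.

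The comparison of Cirrhosis-PTH with Control asks what still differed from corn oil livers in mice given CCl4 and PTH. Matrix and macrophage genes stayed higher. Col1a1 was 60.5 ± 41.6 CPM against 13.3 ± 12.7 CPM in Control (log2 2.19 ± 0.51, adjusted p = 0.014), 2.88 without Control replicate 7, and the call did not hold in the fit of 12 libraries. Of 31 fibrillar and matrix genes 20 were higher, with Fbn1 at 1.27 ± 0.16 and Lum at 2.44 ± 0.32 (camera adjusted p = 5.7e-16, and adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone, 25 were higher and 1 lower. Matrix crosslinking and remodelling genes were higher in 14 of 24 (18 adjusted over the list alone), with Adamts12 at 1.61 ± 0.19 and Mmp2 at 2.86 ± 0.37 (camera adjusted p = 6.3e-12, and adjusted p = 0.19 with an estimated correlation). Fbn2 rose by 6.23 ± 0.70, or 7.12 without Control replicate 7, and Mmp7 by 4.98 ± 0.95, or 6.51 without Control replicate 3, a call that did not hold with voom. Recruited macrophage genes were higher in 11 of 20 (16 adjusted over the list alone), with Cx3cr1 at 2.21 ± 0.23, Trem2 at 3.06 ± 0.32 and Gpnmb, a marker of lipid-laden macrophages, at 5.06 ± 0.60 (5.66 without Control replicate 7). Their camera adjusted p was 3.6e-11, with adjusted p = 0.19 with an estimated correlation. Pde6b, a phosphodiesterase of rod cells, was 0.379 ± 0.229 CPM in Control, 27.1 ± 2.96 CPM in Cirrhosis and 31.6 ± 7.05 CPM in Cirrhosis-PTH, a change of 6.36 ± 0.32 against Control. Hpca rose by 4.42 ± 0.67 and Cpe, carboxypeptidase E, by 3.71 ± 0.81, and the call of Cpe did not hold with voom or with the replicate block.

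Mesothelial markers were above Control too, without the fall of the matrix score from 2.37 ± 0.05 in Cirrhosis to 1.1 ± 0.42 in Cirrhosis-PTH (SD, n = 6). Of 9 mesothelial genes 6 were higher in Cirrhosis-PTH than in Control (8 adjusted over the list alone), with a median of 2.41 (camera adjusted p = 1.9e-05, and adjusted p = 0.25 with an estimated correlation). The mesothelial score was 1.20 ± 0.77 in Cirrhosis and 2.28 ± 0.73 in Cirrhosis-PTH (SD, n = 6). In Cirrhosis 2 of the 9 genes were higher than in Control, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.072). Between Cirrhosis-PTH and Cirrhosis it was not called either (camera adjusted p = 0.32, with score adjusted p = 0.048), with 4 higher and 1 lower, or 6 and 1 adjusted over the list alone.

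Male-biased genes stayed lower. Of 21 members 12 were lower than in Control (14 adjusted over the list alone), with a median of -0.94, also with Moxd1 at its bound (camera adjusted p = 1.2e-16, and adjusted p = 0.098 with an estimated correlation). Hsd3b5 changed by -4.05 ± 0.36 (adjusted p = 8.2e-06) and Susd4, a complement regulator, by -4.82 ± 0.39. Moxd1 had no count in Cirrhosis-PTH and was at least 5159-fold lower than in Control, a call that did not hold with voom. Fitm1 changed by -4.81 ± 0.36, Mup9 by -4.35 ± 0.79 and Mup11 by -3.84 ± 0.44, and the call of Mup9 did not hold with the replicate block. Mitochondrially encoded genes were lower in 2 of 13 members (10 adjusted over the list alone), mt-Co2 at -0.60 ± 0.16 and mt-Co3 at -0.50 ± 0.14 (camera adjusted p = 3.7e-07, and adjusted p = 0.29 with an estimated correlation). Both calls were lost with the replicate block, and that of mt-Co3 in the fit of 12 libraries and without Control replicate 2 (-0.49), 6 (-0.41) or 7 (-0.48) or Cirrhosis-PTH replicate 3 (-0.48) or 6 (-0.39). Cirrhosis-PTH replicate 6 stood apart, with a mitochondrial genome score of -2.15 against -1.09 to 0.01 in the other 5, a mitochondrial ribosomal RNA share of 2.21% against 3.94% to 6.73%, and 195.9 CPM of the small nuclear RNA Rn7sk against 1084 to 1180 CPM. Without it, mt-Co2 in Cirrhosis-PTH vs Control changed by -0.49 and kept its call. Of 38 nuclear oxidative phosphorylation genes 4 were lower (5 adjusted over the list alone), with Ndufb10 at -0.50 ± 0.12 and Ndufb3 at -0.74 ± 0.19, both lost with the replicate block and Ndufb3 also without Control replicates 7 and 8. That list had camera adjusted p = 4.1e-06 (adjusted p = 0.32 with an estimated correlation).

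Some interferon, antigen presentation and fetal genes were also above Control. Interferon response genes were higher in 9 of 36 members (14 adjusted over the list alone), with Oas1a at 1.17 ± 0.15 and Oas3 at 1.15 ± 0.19 (camera adjusted p = 9.6e-07, and adjusted p = 0.29 with an estimated correlation). Antigen presentation genes were higher in 8 of 14 (9 adjusted over the list alone), with Cd74 at 0.74 ± 0.13, lost with the replicate block, and H2-Eb1 at 0.98 ± 0.18 (camera adjusted p = 6.4e-06, and adjusted p = 0.19 with an estimated correlation). In the fetal and tumour-associated list 8 of 20 genes were higher and 1 lower (14 and 1 adjusted over the list alone), with Golm1 at 1.20 ± 0.19 and Tff3 at -3.76 ± 0.70 (camera adjusted p = 4.8e-06, and adjusted p = 0.12 with an estimated correlation). In the stress response list 6 of 25 genes were lower and 1 higher (13 and 1 adjusted over the list alone), with Pdia6 at -0.52 ± 0.11 and Atf3 at 1.73 ± 0.34 (camera adjusted p = 1.9e-05, and adjusted p = 0.28 with an estimated correlation). The call of Pdia6 was lost with the replicate block and that of Atf3 with voom. Of the genes given whatever their result, Krt19 was higher by 2.05 ± 0.42 (adjusted p = 0.0038), and Timp1, at 0.29 ± 0.81, did not pass (adjusted p = 0.88) but reached 2.42 with an adjusted p of 0.012 without Control replicate 7. Acta2 (-0.43 ± 0.40), Cyp2e1 (-0.39 ± 0.20), Cyp7a1 (0.33 ± 0.54), Cyp2b10 (1.59 ± 0.84) and Alb (-0.27 ± 0.14) did not pass.

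In all, 1932 genes differed between Cirrhosis-PTH and Control, 1389 higher and 543 lower, and 905 at least 2-fold (747 higher, 158 lower). The libraries of both groups did not overlap in 979 genes, where chance gives 47.4 (0.216%). Without Control replicates 7 and 8 the number was 1963, and with thinned counts 1795. Of 42 lists, 24 were called, 15 up and 9 down, and 0 with an estimated correlation, where 7 had an unadjusted p under 0.05 and fry called 25. The score test called 28 lists. It alone called the endothelial (score adjusted p = 0.019), CAR and PXR target (0.046), AhR target (0.041), NRF2 (0.033), p53 target (0.0042) and named lncRNA (0.010) lists, and camera alone the Kupffer cell (0.074) and mitochondrial genome (0.051) lists. Of the 4870 genes that differed at least 2-fold between Cirrhosis and Control, the median share of the log2 change still present in Cirrhosis-PTH was 35.2%, being 43.2% for the 3117 higher genes and 22.0% for the 1753 lower genes. Both changes use the same Control libraries, so the share was also taken with separate groups of 3 Control libraries in 20 ordered splits, chosen after it was seen. It then ran from 20.3% to 34.6% (25.8% to 42.9% for higher genes, 10.9% to 24.6% for lower genes), where Control libraries in place of Cirrhosis-PTH gave -4.72% to 17.4% (-5.41% to 19.7% and -3.49% to 13.5%). An equal share of the CPM difference gives a larger share on the log2 scale for genes that rose than for genes that fell. These values therefore cannot show which direction returned further. Cx3cr1, Fbn1, Pdia6, Golm1, Hpca, Timp1, Hsd3b5 and mt-Co3 overlap other genes in the annotation, and Oas1a and the Mup genes have close copies, so their reads may be shared.

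Among lncRNA genes, 2800 were tested, at a median log2 CPM of -1.27 against 2.99 for 14949 protein-coding genes. Between Cirrhosis and Control 918 differed (384 higher, 534 lower), which is 32.8% against 60.2% of the protein-coding genes (Fisher's exact test, p = 9.1e-158). Gm36161, Gm19619 and Dnm3os rose, by 7.12 ± 0.54, 1.84 ± 0.16 and 2.37 ± 0.21, and without Control replicate 6, which held all 7 Control counts of Gm36161, that gene was at least 248-fold higher. 0610031O16Rik and Gm14097 changed by -1.73 ± 0.10 and -3.95 ± 0.24. Gm13872 (ENSMUSG00000087185, GRCm38 chromosome 2, 102737907 to 102746760, inside Slc1a2 on the opposite strand) was at least 376-fold lower in Cirrhosis, where it had no count. Between Cirrhosis-PTH and Cirrhosis 616 differed (454 higher, 162 lower), or 22.0% against 48.3% (Fisher's exact test, p = 1.1e-155). Gm13872 was at least 295-fold higher, 0610031O16Rik and 1700028E10Rik rose by 1.39 ± 0.10 and 2.73 ± 0.23, and Snhg15, Ifi30 and Gm26603 changed by -1.53 ± 0.17, -1.27 ± 0.15 and -0.87 ± 0.14. Ifi30 is better known as a protein-coding gene of lysosomes and is counted here by its biotype in the release used. Between Cirrhosis-PTH and Control 110 differed (81 higher, 29 lower), or 3.93% against 11.1% (Fisher's exact test, p = 7.6e-38). Gm36161 and Gm19619 were higher by 5.26 ± 0.55 and 1.15 ± 0.16 (Gm36161 at least 66.8-fold without Control replicate 6), and A830036E02Rik, without a count in Control, was at least 90.5-fold higher. Gm35696, Gm13775 and Gm14097 changed by -2.63 ± 0.38, -6.81 ± 0.76 and -1.35 ± 0.22, and Gm13775 by -7.92 without Cirrhosis-PTH replicate 2. Fisher's test treats genes as independent, and lncRNA and coding genes were not matched for level. Gm13872, 0610031O16Rik, Gm14097, Dnm3os, 1700028E10Rik, Gm26603 and A830036E02Rik overlap a coding gene on the opposite strand, so with no stated strand their reads cannot be told from that gene's.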

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

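In each group of 6 mice, the highest and the lowest library were compared with the nearest of the others for the library measures, the named genes and the list scores. Of 444 groups of values, 35 had a library far from the others, where chance alone gives about 1 in 20, or 22.2. The tests of the hepatocyte share in Cirrhosis, the library order, a common remaining share, the time since the injection, Cyp2e1 and female mice were chosen after the result was seen, as was leaving out Control replicates 7 and 8 and thinning the counts.

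Control replicate 7 lay far above the other 5 Control libraries for Col1a1 (38.8 CPM), Fbn2 (0.242), Mmp2 (5.02), Timp1 (1.15) and Trdc (0.551). Control replicate 3 lay above them for Mmp7 (0.254) and Oas3 (2.30) and below them for the p53 target score (-0.15). Control replicate 6 lay above them for Gm36161 (0.0710) and Sprr1a (0.0304) and below them for Slc10a2 (3.82). Control replicate 8 was high for Dnm3os (2.16) and the neutrophil score (2.43), Control replicate 2 was high for the red cell score (0.96), and Control replicate 1 was low for Glul (519.8). In Cirrhosis, replicate 3 was high for Col1a1 (290.3) and Hpd (521) and low for the matrix crosslinking score (2.58) and the cytokine score (1.57). Replicate 2 was high for Mup12 (73.1), the neutrophil score (6.60) and the number of genes with at least 10 counts (22966), replicate 1 was high for Mup9 (12.5), and replicate 5 was low for the dendritic cell score (0.88). In Cirrhosis-PTH, replicate 3 was high for Cd74 (98.9), Lum (56.6) and Susd4 (2.95) and low for Ndufb5 (24.3) and Otc (169.5). Replicate 1 was high for 6430548M08Rik (8.93) and low for Glul (309) and the B and plasma cell score (0.13), replicate 6 was high for Cyp2b10 (2.03) and low for Ifi30 (5.31), and replicate 2 was high for Gm13775 (0.369). No explanation was tested for these single libraries.

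The number of genes that differed between Cirrhosis-PTH and Cirrhosis, 8464, was weighed first. Thinning every library left 92.8% of these genes called in the same direction, which argues against depth and the ribosomal RNA share as its whole cause. An even loss of all hepatocytes in Cirrhosis would move hepatocyte genes alike, but the pericentral median was -1.91 against a lower quartile of -1.05 for secreted proteins. That argues against an even loss as the whole cause. An uneven loss of hepatocytes could not be tested this way. Library numbers run in blocks by group, with 2 changes of group along them, so a processing batch that followed the order and the treatment cannot be told apart. Chance in how mice fell into groups is argued against for each comparison, since 1 of 100 splits drawn, the real one, gave as many genes. The numbers were 11073 against a highest other of 4890 for Cirrhosis against Control, 8464 against 3426 for Cirrhosis-PTH against Cirrhosis, and 1932 against 372 for Cirrhosis-PTH against Control. A share of 1 in 100 is the smallest these splits can give, and they do not bear on a batch that followed the library order.

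The mean share of the CCl4 change that remained with PTH was lower in 5 stress lists than in 3 matrix and macrophage lists, grouped after the shares were seen. Over the 6 Cirrhosis-PTH mice (mean ± SD), 19.9% ± 7.26 of the score change remained in the p53 target list, 15.8% ± 5.23 in the NRF2 list, 8.0% ± 8.45 in the immediate early list, -8.0% ± 14.9 in the heat shock list and -15.8% ± 4.16 in the unfolded protein list, the last a fall below Control. The matrix, crosslinking and macrophage lists kept 46.4% ± 17.8, 41.2% ± 12.1 and 44.4% ± 10.8. An exact sign-flip test (p = 0.031) therefore decides nothing between the sets, but 1 share of the log2 score change common to all 8 lists is argued against: at the share that went best with them, 11.8%, the macrophage and unfolded protein scores differed from it (Welch's t, p = 0.033 and 0.034 adjusted for all 42 lists), while crosslinking (0.10), fibrillar (0.22) and the other 4 stress lists (1) did not pass. An equal share of the CPM change leaves a larger log2 share in lists that rose further. The matrix and macrophage lists had risen furthest, with mean Cirrhosis scores of 2.37, 2.96 and 3.43 against at most 2.16 in the stress lists. A common share of the CPM change was not tested and stays open. A longer time between the last injection and sampling may separate short-lived from long-lived responses, and 0 label fields give that time, so it cannot be told apart from an effect of PTH. A lower conversion of CCl4 through Cyp2e1 stays open. The change of its messenger RNA against Control was -0.39 with a 95% interval of -0.82 to 0.04. That level was measured once, after 12 weeks, and is not enzyme activity at the injections, so it cannot decide the question.

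Male-biased genes stayed low in Cirrhosis-PTH. Female mice are excluded, with a lowest Ddx3y of 43.0 CPM and a highest Xist of 1.71 CPM over the 18 libraries. An even loss of all hepatocytes is argued against as the whole cause by a median of -0.94 against a lower quartile of -0.25 for secreted proteins. Leaving out Control replicates 7 and 8 kept 100% of the 12 genes called lower. The list lay at percentile 2.64 of 10000 random lists matched for level and fall, but the matched genes had fallen by 2.38 and the list by 2.90, a gap noticed after the value was seen, and with the 5th percentile moved for that gap to -1.0 the planned limit was wrong and baseline level cannot be told apart. Beyond these, no biological explanation was tested.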

How the results depend on the processing

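Leaving out Control replicates 7 and 8, thinning and leaving out the ribosomal RNA loci were chosen after seeing the data. Of 155 named gene results, all kept direction and side of the threshold under RLE and upper-quartile scaling, DESeq2 and no filter, 151 under voom, 152 in fits of 12 libraries and 142 against a fold change of 1.5. Scaling moved the median log2 change by at most 0.03. Each method takes most genes as unchanged, which that closeness does not test, and 11073 of 21914 genes differed in Cirrhosis against Control. TMM factors were 0.782 ± 0.125 in Control, 1.29 ± 0.0607 in Cirrhosis and 1.01 ± 0.144 in Cirrhosis-PTH (SD, n = 6). They differed against Control in Cirrhosis (exact permutation adjusted p = 0.0195) and Cirrhosis-PTH (0.0292), and between the CCl4 groups (0.0195). Without 1 library, the numbers of genes that differed were 10385 to 11142, 7724 to 8604 and 1293 to 2009 in Cirrhosis against Control, Cirrhosis-PTH against Cirrhosis and Cirrhosis-PTH against Control, with 6853 to 7622 opposed genes. The lowest for Cirrhosis-PTH against Control was without Cirrhosis-PTH replicate 3. Against a fold change of 1.5, 4804, 2440 and 428 genes passed, as a stricter hypothesis requires. DESeq2 called 166 lncRNA genes in Cirrhosis-PTH against Control, where edgeR called 110, and the cause was not tested. With an estimated correlation 4, 1 and 0 lists passed, where the preset correlation gave 34, 30 and 24, since the test then widens with the spread shared by a list's genes. For 0 lists, 7 had an unadjusted p under 0.05 and fry called 25. With the replicate block the numbers were 9526, 8219 and 1354 genes, 6777 opposed genes and 35, 30 and 24 lists, with 10 of 155 named gene results no longer passing and fewer residual degrees of freedom. Results that did not pass and changed sign with 1 library left out were Krt19 in Cirrhosis-PTH vs Cirrhosis (-0.47 to 0.12) and Timp1 in Cirrhosis-PTH vs Control (-0.00767 to 2.42), and the cause was not tested. Separate Cirrhosis libraries for each comparison gave at least 3.80 times the opposed genes of independent lists. Removing trends on GC content and transcript length left 98.8% of the calls of Cirrhosis-PTH against Cirrhosis past 2 standard errors. Thinning to 24513979 counts per library left 10451, 8158 and 1795 genes, so depth limited the calls by little, and leaving out the ribosomal RNA loci gave 11024, 8452 and 1946.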

Other observations

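Clock genes moved with CCl4 and moved back with PTH. The genes named in this part were chosen after their values were seen. Dbp, Nr1d1 and Per2 changed by -2.02 ± 0.18, -1.63 ± 0.12 and -0.59 ± 0.13 in Cirrhosis (log2 ± SE), while Arntl, which peaks in the opposite phase, changed by 1.97 ± 0.19. With PTH the changes were 1.71 ± 0.17, 0.96 ± 0.12, 0.60 ± 0.13 and -1.54 ± 0.18. Against Control, Nr1d1 was still lower in Cirrhosis-PTH by -0.67 ± 0.12 (adjusted p = 0.0013). Of 20 core clock genes, 4 rose and 12 fell in Cirrhosis, 13 rose and 4 fell with PTH, and 2 were higher and 2 lower in Cirrhosis-PTH than in Control (4, 12, 13, 5, 2 and 2 adjusted over the list alone). The core clock medians were -0.80, 0.67 and 0.03 in that order, with camera adjusted p = 0.0044, 0.0024 and 0.55, and adjusted p = 0.15, 0.12 and 0.84 with an estimated correlation. The hour of sampling is not given.

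Most neutrophil and B cell genes passed the threshold as higher in Cirrhosis, and 5 of 19 T and natural killer cell genes did. The list scores of T and NK cells and of B and plasma cells nevertheless rose by similar amounts. They were 1.04 ± 0.23 and 1.09 ± 0.24 in Cirrhosis (SD, n = 6), with Control SDs of 0.18 and 0.50. S100a8 and S100a9 rose by 4.27 ± 0.96 and 4.23 ± 1.05 and changed with PTH by -2.76 ± 0.85 and -2.54 ± 0.92. Ncr1, a receptor of natural killer cells, had no count in Control and was at least 46.5-fold higher in Cirrhosis and at least 61.1-fold higher in Cirrhosis-PTH, while Cd3e did not pass in either (0.68 ± 0.37 and 0.25 ± 0.38). Of 12 neutrophil genes, 11 rose and 0 fell in Cirrhosis, 0 rose and 10 fell with PTH, and 2 were higher and 0 lower in Cirrhosis-PTH than in Control (11, 0, 0, 11, 3 and 0 adjusted over the list alone). The neutrophil medians were 4.14, -2.57 and 1.38 in that order, with camera adjusted p = 0.00018, 0.0024 and 0.00092, and adjusted p = 0.26, 0.36 and 0.35 with an estimated correlation. Single libraries stood apart in the neutrophil score. Cirrhosis replicate 2 was at 6.60 against 2.65 to 3.60 in the rest of its group, and Control replicate 8 at 2.43 against -1.35 to -0.21. Of 19 T and NK cell genes, 5 rose and 0 fell in Cirrhosis, 1 rose and 0 fell with PTH, and 2 were higher and 0 lower in Cirrhosis-PTH than in Control (4, 0, 0, 0, 3 and 0 adjusted over the list alone). The T and NK cell medians were 0.64, -0.26 and 0.39 in that order, with camera adjusted p = 0.038, 0.47 and 0.0095, and adjusted p = 0.22, 0.68 and 0.25 with an estimated correlation. The T and NK cell call in Cirrhosis did not hold without Control replicate 1 (adjusted p = 0.066), without Cirrhosis replicate 2 (0.065) or without Cirrhosis-PTH replicate 4 (0.050). Of 14 B and plasma cell genes, 9 rose and 0 fell in Cirrhosis, 0 rose and 3 fell with PTH, and 3 were higher and 0 lower in Cirrhosis-PTH than in Control (10, 0, 0, 3, 6 and 1 adjusted over the list alone). The B and plasma cell medians were 0.86, -0.28 and 0.67 in that order, with camera adjusted p = 0.0055, 0.16 and 0.0049, and adjusted p = 0.23, 0.52 and 0.29 with an estimated correlation. Of 14 Kupffer cell genes, 3 rose and 6 fell in Cirrhosis, 2 rose and 4 fell with PTH, and 0 were higher and 1 lower in Cirrhosis-PTH than in Control (3, 6, 2, 4, 0 and 4 adjusted over the list alone). The Kupffer cell medians were -0.06, -0.32 and -0.25 in that order, with camera adjusted p = 0.42, 0.37 and 0.0023, and adjusted p = 0.77, 0.77 and 0.35 with an estimated correlation. The Kupffer cell call in Cirrhosis-PTH against Control did not hold with fry or with the replicate block.

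The mesothelial genes Lrrn4, Msln, Wt1 and Upk3b lay above Control in Cirrhosis-PTH by 2.45 ± 0.57, 2.72 ± 0.81, 2.41 ± 0.45 and 2.26 ± 0.74, the last not passing. Female-biased, interferon and antigen presentation lists were also higher in Cirrhosis-PTH than in Control. Of 17 female-biased liver genes, 7 rose and 1 fell in Cirrhosis, 3 rose and 4 fell with PTH, and 3 were higher and 0 lower in Cirrhosis-PTH than in Control (7, 1, 3, 4, 9 and 0 adjusted over the list alone). The female-biased liver medians were 1.1, -0.09 and 1.1 in that order, with camera adjusted p = 0.034, 0.69 and 0.00031, and adjusted p = 0.29, 0.81 and 0.19 with an estimated correlation. In Cirrhosis-PTH against Cirrhosis the female-biased median was negative and its mean positive. Of 36 interferon response genes, 27 rose and 0 fell in Cirrhosis, 2 rose and 14 fell with PTH, and 9 were higher and 0 lower in Cirrhosis-PTH than in Control (29, 2, 2, 14, 14 and 0 adjusted over the list alone). The interferon response medians were 0.65, -0.38 and 0.38 in that order, with camera adjusted p = 3.0e-05, 0.013 and 9.6e-07, and adjusted p = 0.29, 0.55 and 0.29 with an estimated correlation. That call in Cirrhosis-PTH against Cirrhosis did not hold without Cirrhosis replicate 5 (adjusted p = 0.050). Of 14 dendritic cell and antigen presentation genes, 11 rose and 0 fell in Cirrhosis, 0 rose and 7 fell with PTH, and 8 were higher and 0 lower in Cirrhosis-PTH than in Control (12, 0, 0, 7, 9 and 0 adjusted over the list alone). The dendritic cell and antigen presentation medians were 1.36, -0.52 and 0.72 in that order, with camera adjusted p = 0.00015, 0.018 and 6.4e-06, and adjusted p = 0.13, 0.31 and 0.19 with an estimated correlation. Of 22 sinusoidal and vascular endothelial genes, 7 rose and 2 fell in Cirrhosis, 1 rose and 5 fell with PTH, and 3 were higher and 0 lower in Cirrhosis-PTH than in Control (7, 2, 1, 4, 5 and 0 adjusted over the list alone). The sinusoidal and vascular endothelial medians were 0.14, -0.08 and 0.02 in that order, with camera adjusted p = 0.17, 0.34 and 0.25, and adjusted p = 0.37, 0.55 and 0.54 with an estimated correlation. The endothelial score passed in all 3 (adjusted p = 0.0042, 0.0074 and 0.019), and fry in the first and the last (adjusted p = 0.00050, 0.13 and 0.028).

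Cholesterol and lipid genes fell with CCl4 and rose with PTH. Of 25 cholesterol synthesis genes, 4 rose and 16 fell in Cirrhosis, 18 rose and 0 fell with PTH, and 3 were higher and 0 lower in Cirrhosis-PTH than in Control (4, 16, 19, 0, 5 and 0 adjusted over the list alone). The cholesterol synthesis medians were -0.64, 0.82 and 0.24 in that order, with camera adjusted p = 0.0013, 6.1e-07 and 0.062, and adjusted p = 0.37, 0.25 and 0.76 with an estimated correlation. Of 25 lipogenesis genes, 3 rose and 13 fell in Cirrhosis, 15 rose and 4 fell with PTH, and 2 were higher and 1 lower in Cirrhosis-PTH than in Control (3, 14, 16, 4, 2 and 2 adjusted over the list alone). The lipogenesis medians were -0.57, 0.54 and -0.03 in that order, with camera adjusted p = 0.0034, 0.0010 and 0.64, and adjusted p = 0.22, 0.17 and 0.89 with an estimated correlation. Of 32 fatty acid oxidation and PPARA target genes, 4 rose and 21 fell in Cirrhosis, 19 rose and 4 fell with PTH, and 0 were higher and 1 lower in Cirrhosis-PTH than in Control (4, 21, 23, 4, 0 and 0 adjusted over the list alone). The fatty acid oxidation and PPARA target medians were -0.50, 0.58 and -0.04 in that order, with camera adjusted p = 0.00068, 3.4e-05 and 0.73, and adjusted p = 0.37, 0.31 and 0.92 with an estimated correlation. Of 23 gluconeogenesis and glycolysis genes, 6 rose and 13 fell in Cirrhosis, 10 rose and 5 fell with PTH, and 2 were higher and 1 lower in Cirrhosis-PTH than in Control (6, 13, 10, 5, 2 and 1 adjusted over the list alone). The gluconeogenesis and glycolysis medians were -0.36, 0.34 and -0.05 in that order, with camera adjusted p = 0.12, 0.16 and 0.82, and adjusted p = 0.37, 0.47 and 0.92 with an estimated correlation. In Cirrhosis-PTH against Control the medians of the lipogenesis, fatty acid oxidation, core clock, cytochrome P450, AhR target and NRF2 lists differed in sign from their means, camera directions or scores. Camera called none of these lists, while the score test called the AhR target and NRF2 lists, as given above.

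Heat shock, oxidant and immediate early genes rose with CCl4. Hspa1a and Fos changed by 3.29 ± 0.51 and 3.90 ± 0.40 in Cirrhosis and by -3.60 ± 0.51 and -3.28 ± 0.37 with PTH, and Egr1 was lower in Cirrhosis-PTH than in Control (-1.76 ± 0.39). Of 16 heat shock genes, 12 rose and 0 fell in Cirrhosis, 0 rose and 11 fell with PTH, and 0 were higher and 0 lower in Cirrhosis-PTH than in Control (12, 0, 0, 11, 0 and 0 adjusted over the list alone). The heat shock medians were 0.77, -0.85 and -0.17 in that order, with camera adjusted p = 0.0053, 6.1e-05 and 0.26, and adjusted p = 0.37, 0.28 and 0.84 with an estimated correlation. Of 20 immediate early genes, 18 rose and 1 fell in Cirrhosis, 0 rose and 17 fell with PTH, and 4 were higher and 1 lower in Cirrhosis-PTH than in Control (18, 1, 0, 17, 4 and 1 adjusted over the list alone). The immediate early medians were 2.21, -2.06 and 0.10 in that order, with camera adjusted p = 5.5e-07, 1.0e-09 and 0.51, and adjusted p = 0.13, 0.090 and 0.89 with an estimated correlation. Of 27 NRF2 and glutathione genes, 16 rose and 3 fell in Cirrhosis, 2 rose and 17 fell with PTH, and 2 were higher and 2 lower in Cirrhosis-PTH than in Control (18, 3, 2, 18, 3 and 2 adjusted over the list alone). The NRF2 and glutathione medians were 0.61, -0.67 and -0.04 in that order, with camera adjusted p = 0.00056, 6.3e-06 and 0.76, and adjusted p = 0.20, 0.10 and 0.92 with an estimated correlation. Of 9 AhR target genes, 4 rose and 2 fell in Cirrhosis, 2 rose and 3 fell with PTH, and 2 were higher and 0 lower in Cirrhosis-PTH than in Control (4, 2, 2, 3, 2 and 0 adjusted over the list alone). The AhR target medians were 0.45, -0.53 and -0.05 in that order, with camera adjusted p = 0.25, 0.34 and 0.55, and adjusted p = 0.32, 0.41 and 0.67 with an estimated correlation. Of 22 CAR and PXR target genes, 5 rose and 12 fell in Cirrhosis, 14 rose and 4 fell with PTH, and 4 were higher and 2 lower in Cirrhosis-PTH than in Control (5, 12, 15, 4, 5 and 3 adjusted over the list alone). The CAR and PXR target medians were -0.54, 0.79 and 0.29 in that order, with camera adjusted p = 0.035, 0.00087 and 0.18, and adjusted p = 0.37, 0.22 and 0.67 with an estimated correlation. For CAR and PXR targets in Cirrhosis the median was negative and the mean score positive (0.29).

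Cell type and liver function lists not given in every comparison above follow in the same order. Of 25 stellate cell and myofibroblast genes, 18 rose and 1 fell in Cirrhosis, 1 rose and 18 fell with PTH, and 8 were higher and 1 lower in Cirrhosis-PTH than in Control (19, 1, 1, 20, 8 and 2 adjusted over the list alone). The stellate cell and myofibroblast medians were 1.34, -0.84 and 0.10 in that order, with camera adjusted p = 7.2e-06, 4.3e-06 and 0.010, and adjusted p = 0.13, 0.10 and 0.35 with an estimated correlation. Of 18 cholangiocyte and ductular genes, 14 rose and 1 fell in Cirrhosis, 0 rose and 8 fell with PTH, and 5 were higher and 0 lower in Cirrhosis-PTH than in Control (14, 1, 0, 8, 10 and 1 adjusted over the list alone). The cholangiocyte and ductular medians were 1.87, -0.70 and 0.87 in that order, with camera adjusted p = 6.3e-05, 0.0018 and 0.00030, and adjusted p = 0.20, 0.30 and 0.29 with an estimated correlation. Of 40 cell cycle genes, 30 rose and 1 fell in Cirrhosis, 2 rose and 18 fell with PTH, and 4 were higher and 0 lower in Cirrhosis-PTH than in Control (31, 1, 2, 19, 6 and 0 adjusted over the list alone). The cell cycle medians were 1.34, -0.79 and 0.50 in that order, with camera adjusted p = 8.1e-08, 1.0e-05 and 6.8e-05, and adjusted p = 0.099, 0.12 and 0.26 with an estimated correlation. Of 20 hepatocyte secreted protein genes, 0 rose and 19 fell in Cirrhosis, 17 rose and 1 fell with PTH, and 0 were higher and 1 lower in Cirrhosis-PTH than in Control (0, 19, 17, 1, 0 and 2 adjusted over the list alone). The hepatocyte secreted protein medians were -0.71, 0.68 and -0.18 in that order, with camera adjusted p = 3.8e-09, 3.5e-08 and 0.00015, and adjusted p = 0.13, 0.12 and 0.30 with an estimated correlation. Of 13 mitochondrial genome genes, 0 rose and 13 fell in Cirrhosis, 1 rose and 0 fell with PTH, and 0 were higher and 2 lower in Cirrhosis-PTH than in Control (0, 13, 0, 0, 0 and 10 adjusted over the list alone). The mitochondrial genome medians were -1.11, 0.35 and -0.71 in that order, with camera adjusted p = 0.00055, 0.32 and 3.7e-07, and adjusted p = 0.37, 0.77 and 0.29 with an estimated correlation.

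Acute phase and red cell genes were not called as lists in any comparison. Saa1 was 709.8 CPM in Control replicate 7, 1077 in Control replicate 8 and 962 in Cirrhosis replicate 2, and 6.77 to 321 CPM in the other libraries. Of 29 acute phase genes, 7 rose and 2 fell in Cirrhosis, 3 rose and 6 fell with PTH, and 0 were higher and 0 lower in Cirrhosis-PTH than in Control (6, 2, 3, 6, 0 and 0 adjusted over the list alone). The acute phase medians were -0.09, -0.38 and -0.08 in that order, with camera adjusted p = 0.50, 0.37 and 0.83, and adjusted p = 0.84, 0.79 and 0.95 with an estimated correlation. In Cirrhosis the acute phase median was negative and the mean score positive (0.58). Of 8 red cell genes, 0 rose and 1 fell in Cirrhosis, 1 rose and 0 fell with PTH, and 0 were higher and 0 lower in Cirrhosis-PTH than in Control (0, 1, 1, 0, 0 and 0 adjusted over the list alone). The red cell medians were -0.31, 0.16 and -0.10 in that order, with camera adjusted p = 0.17, 0.26 and 0.61, and adjusted p = 0.59, 0.68 and 0.89 with an estimated correlation. Of 45 named lncRNA genes, 20 rose and 8 fell in Cirrhosis, 9 rose and 13 fell with PTH, and 7 were higher and 2 lower in Cirrhosis-PTH than in Control (21, 9, 9, 14, 7 and 2 adjusted over the list alone). The named lncRNA medians were 0.40, -0.20 and 0.16 in that order, with camera adjusted p = 0.12, 0.37 and 0.11, and adjusted p = 0.30, 0.55 and 0.32 with an estimated correlation. Meg3 was higher in Cirrhosis-PTH than in Control by 2.46 ± 0.42.

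In Cirrhosis-PTH against Control, pericentral genes were lower in 6 and higher in 1 of 20 (8 and 2 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 5.8e-05, and adjusted p = 0.25 with an estimated correlation). Coagulation and complement genes were lower in 2 of 27, or 3 adjusted over the list alone (camera adjusted p = 0.00049, and adjusted p = 0.42 with an estimated correlation), and bile acid genes lower in 8 and higher in 2 of 33, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00065, and adjusted p = 0.30 with an estimated correlation). Neither of these calls held with fry. Cytochrome P450 genes were higher in 4 and lower in 4 of 39, and p53 targets higher in 4 and lower in 1 of 20, neither called by camera (adjusted p = 0.25 and 0.11). The score test called the p53 target list, as given above. Cytokine and chemokine genes were higher in 6 of 29 (camera adjusted p = 0.00049, and adjusted p = 0.29 with an estimated correlation). Of 34 urea cycle and amino acid catabolism genes edgeR called 0 (4 at an unadjusted p under 0.05), DESeq2 2 and limma voom 0, and of 21 periportal genes edgeR called 0 (3 unadjusted), DESeq2 1 and limma voom 0. For the 29 acute phase genes these numbers were 0 (3 unadjusted), 2 and 2, for the 16 heat shock genes 0 (3 unadjusted), 1 and 0, and for the 8 red cell genes 0 with each tool, also unadjusted. Periportal genes had risen with PTH against Cirrhosis in 15 of 21 (camera adjusted p = 1.0e-05, and adjusted p = 0.25 with an estimated correlation).

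Nnt, a gene whose sequence differs between C57BL/6 substrains, was 11.1 CPM in Cirrhosis-PTH replicate 1 and 39.6 to 105 CPM in the other 17 libraries, and the labels give no substrain. Afp, the fetal albumin-like gene, averaged 1.87 ± 0.876 CPM in Control, 2.68 ± 0.668 in Cirrhosis and 2.98 ± 0.723 in Cirrhosis-PTH (SD, n = 6).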
